A study of Mus musculus with 4 samples.

How the data were processed

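Pancreatic islets, the hormone-secreting clusters of the pancreas, were isolated from wild-type mice and from mice lacking Tspan7, an X-linked gene for a tetraspanin membrane protein (genotype Tspan7 y/-). Per the labels' protocols, the islets were kept in Trizol, total RNA was purified on Zymo columns, and libraries were made with a directional kit that marks the strand of each transcript. The labels give 2 control and 2 Tspan7 knockout libraries. The sample labels say knockout, while the text on the whole series says knockdown. The groups were taken from the sample labels.

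The deposited table holds raw counts per Ensembl gene for each library, made by the authors. The submitters' processing notes name HISAT2, featureCounts and the genome build GRCm39, with no versions. The annotation release, the use of strand in counting and the treatment of reads that map to several places are not given in the sources used here. Counts of genes that overlap on opposite strands, or that have near-identical copies elsewhere, are therefore uncertain. Of 13765 genes with a total above 100 counts, 13 had the same 4 counts as another gene. Gene names were looked up in GENCODE release M21, built on GRCm38, which matched 52403 of the 52636 identifiers. Because the builds differ, the reference was used for names and for which genes neighbour each other, and no coordinates are given.

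Library totals ranged from 7855665 to 9377220 counts. At these depths 3 counts, taken as the detection floor, correspond to between 0.320 and 0.382 CPM. All counting intervals cover counting error only, since the reads carried no molecular identifiers. No label says that the libraries came from separate animals. The p-values therefore measure the spread between these samples, which may be technical. The number of counts that differed between any 2 libraries exceeded sampling noise (chi-square per degree of freedom from 7.08 to 20.0, over genes with at least 20 counts in the pair), so each library was counted as 1 sample.

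The counts were analysed in edgeR 4.0.16 under R 4.3.3, with limma 3.58.1. Genes were kept by filterByExpr with its minimum count of 10, which left 16924 genes, and libraries were scaled by the trimmed mean of M-values. The 2 groups were compared with the robust quasi-likelihood F test, two-sided, with no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold change. Log2 fold changes are knockout against control, each with a standard error (SE) or a 95% confidence interval (CI) from the quasi-likelihood fit. CPM values are means ± SD over the 2 libraries of a group, after scaling. Every adjusted p of a single gene comes from this edgeR test unless another tool is named.

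Before the data were examined, 39 gene lists covering islet function, quality signs and other cell types were fixed. Of these, 36 were tested with edgeR's camera at its preset inter-gene correlation of 0.01, two-sided, and adjusted over the lists. Camera asks whether the genes of a list rank higher or lower than the other tested genes. It was repeated with a correlation estimated for each list, and fry was run as a second set test. The list of Y-linked genes and Xist checked the labels and was not tested. The lymphocyte and red blood cell lists had 2 tested members each, under the minimum of 3. They summed to 109 and 123 counts in the control libraries and 94 and 138 in the knockout libraries.

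The genes named were also fixed by rule. Tspan7 came first. Up to 12 genes per direction past the threshold followed, with both libraries of one group above both of the other, a mean log2 CPM of at least 1 and a symbol other than a predicted gene name. Where fewer than 6 passed, genes of smallest unadjusted p filled the list to 6. Up to 4 members of each list with the smallest p were added, and Ins1, Ins2, Gcg, Sst, Ppy, Iapp and Sytl5 were always included. Of the list members selected in this way the text gives examples, and a result for one of them is not reported here. Gm14862 and the genes of the clock test were chosen after their values were seen.

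The pipeline was tested on simulated counts for the 16924 genes with 200 genes changed, drawn among those with a mean log2 CPM of at least 1. Of 50 genes per size, it called 4% at 1.5-fold, 48% at 2-fold, 84% at 3-fold and 92% at 4-fold. Of all calls, 12.7% were false (17 of 134), above the nominal 5%. With the 27 interferon genes lowered by a log2 change of -0.8, camera gave that list an adjusted p of 1.04e-23 and called 0 of the 35 other lists. The estimated correlation gave the same lowered list an adjusted p of 0.388. With 2 residual degrees of freedom it missed a list that was lowered by construction. The simulated genes varied independently, so false list calls among genes that vary together were not tested. In the real libraries the estimated correlation was 0.314 for the interferon list, -0.0113 for antigen presentation, 0.0472 for inflammation and 0.545 for macrophage markers. It was 0.834 for immediate-early genes and 0.867 for acinar markers.

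Alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, the replicate number as a block, the mean of the acinar markers as a covariate, and each library left out in turn. A crossed pairing of replicate numbers was added after the data were seen. In the tests of explanations, 3 changes were made after values were seen. A permutation of genes was added to the comparison of macrophage and interferon genes, a gene lying inside Lancl3 was taken out of the genes between Tspan7 and Lancl3, and the opposite arm of the clock was required to be lower, as the words of that prediction had said and its numeric bound, which was met, had not. Tests of the acinar and immediate-early lists against gaps between libraries of 1 group are given as values only. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.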

Results

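RNA was sequenced from whole pancreatic islets of 2 groups of mice, with 2 control libraries from wild-type animals and 2 libraries from Tspan7 knockout animals. Control replicates 1 and 2 held 8704271 and 9140275 counts, and knockout replicates 1 and 2 held 9377220 and 7855665. The 10 most abundant features took between 7.68% and 9.17% of each library. The comparison asks how the loss of Tspan7 alters islet gene expression in a study of beta-cell exocytosis, the calcium-triggered release of insulin granules.

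Tspan7 (ENSMUSG00000058254) was nearly absent from the knockout libraries. It had 1924 and 1795 counts in the control libraries and 3 and 2 counts in the knockout libraries, or 209 ± 26.1 CPM against 0.288 ± 0.033 CPM (SD, n = 2 each). The knockout level was 0.140% of the control level, with a 95% counting interval of 0.0454% to 0.327% (exact binomial). The fitted log2 fold change was -9.42 ± 0.25 (SE), with an adjusted p of 3.51e-06 in edgeR's quasi-likelihood test. The groups named in the labels therefore matched the targeted gene in all 4 libraries. The Y-linked genes Ddx3y and Uty gave between 851 and 2211 counts in each library, and Xist, the X-inactivation RNA of females, gave 10 to 39.

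Tspan7 was the only gene that passed the threshold, with 0 genes higher and 1 lower among 16924 tested by edgeR. At an unadjusted p under 0.05 there were 263 genes higher and 331 lower, 594 in all, where chance alone would give 846. DESeq2 called 0 higher and 4 lower (Tspan7, Lancl3, Oasl2 and B2m), and limma-voom 0 and 1. Libraries of a single group differed about as much as libraries of different groups, with correlations of log2 CPM across genes of 0.976 and 0.981 within groups and 0.966 to 0.984 between them. The principal component with the largest share of the variance (53.4%) set control replicate 2 apart from knockout replicate 2. The next component (24.4%) placed control replicates 1 and 2 at -25.1 and -5.29, and knockout replicates 1 and 2 at 27.4 and 3.04. It thus separated the groups, mostly through replicate 1 of each. Without control replicate 1 the counts were 33 higher and 15 lower, and without control replicate 2 they were 0 and 2.

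After Tspan7, the gene with the smallest p was Lancl3 (ENSMUSG00000047344), a member of the lanthionine synthetase-like family that lies near Tspan7 on the X chromosome. Lancl3 measured 18.9 ± 6.58 CPM in control and 2.20 ± 0.116 CPM in knockout islets, a log2 fold change of -3.08 ± 0.33 (adjusted p = 0.0917). The genes named next follow the naming rule, which leaves out predicted gene names. 4930539E08Rik, left out by it, did not pass here but was called lower with no low-count filter (log2 fold change -1.35, adjusted p = 1.49e-06). It was also called with the likelihood ratio test (-1.36, 0.00164) and the replicate block (-1.39, 0.00460). The genes named on the lower side all had an adjusted p of 0.684 and did not pass. Oasl2, an interferon-induced gene of the oligoadenylate synthetase family, had a log2 fold change of -1.39 ± 0.21, and Irf7, a transcription factor of the interferon response, -1.37 ± 0.24. Nebl, which encodes an actin-binding protein, stood at -1.14 ± 0.19. B2m, the light chain of class I major histocompatibility molecules, measured 181 ± 12.9 CPM against 97.5 ± 9.99 CPM, a log2 fold change of -0.89 ± 0.14. On the higher side no gene passed. Wdfy1, an endosomal protein gene, came first at 27.1 ± 1.83 CPM in control and 51.6 ± 3.75 CPM in knockout islets (log2 fold change 0.93 ± 0.15, adjusted p = 0.684). Rabepk followed at 0.91 ± 0.17, the clock-controlled transcription factor Hlf at 1.15 ± 0.28, the antisense RNA Nr6a1os at 1.71 ± 0.46, the activity-dependent transcription factor Npas4 at 0.79 ± 0.22 (0.51 without control replicate 2) and Dcdc2a at 0.58 ± 0.16.

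**Figure D1:**
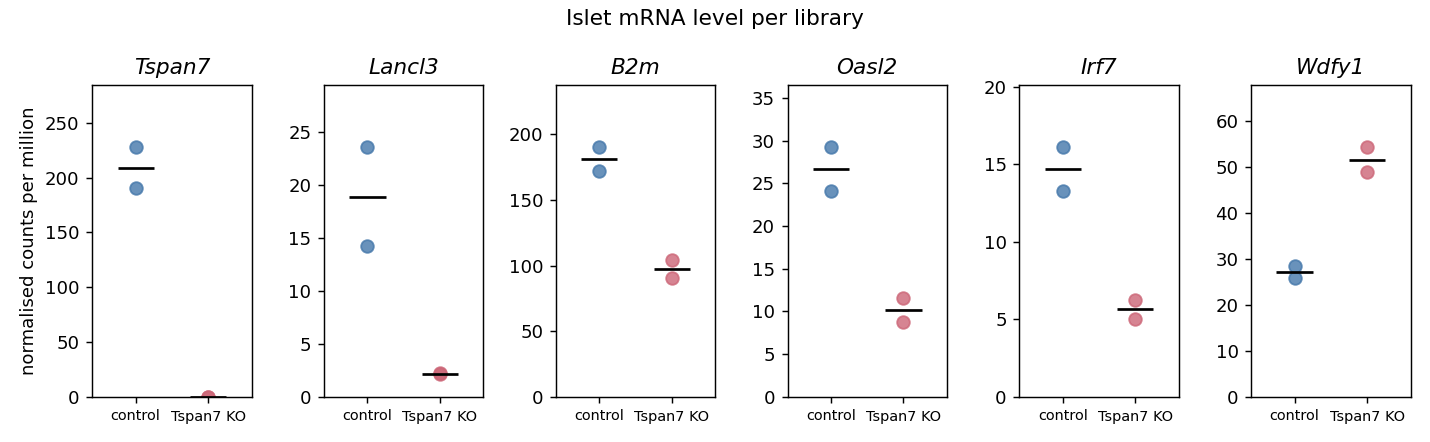
Normalised counts (CPM) in each library for Tspan7, Lancl3, B2m, Oasl2, Irf7 and Wdfy1, with 1 point per library, control in blue, knockout in red, and a line at each group's mean (n = 2 per group). The 2 groups do not overlap for any of the 6 genes, and among them only Tspan7, at 209 CPM against 0.288 CPM, passed the threshold.

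Genes of the interferon response were lower in knockout islets as a group. Of 27 tested members 25 had a negative log2 fold change, 17 of them at an unadjusted p under 0.05, and the median was -0.89. None passed over all genes, and 14 were lower when adjusted over the list alone. In 20 members both knockout libraries lay below both control libraries, an arrangement that chance gives 1 gene in 6 for genes taken singly. Members that vary together can be ordered this way at once, so the 20 are not separate pieces of evidence. Besides Oasl2 and Irf7, the antiviral GTPase gene Mx1 had a log2 fold change of -2.14 ± 0.44 and the antiviral gene Rsad2 of -0.92 ± 0.21 (-0.58 without control replicate 1). Camera gave the list an adjusted p of 5.14e-33 at its preset correlation, and the adjusted p was 0.539 with an estimated correlation. Without control replicate 1 the median was -0.58.

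Antigen presentation genes were lower as well. All 16 tested members had negative values, with a median of -0.51 and a range of -1.59 to -0.23, and in all 16 the 2 groups did not overlap. Of these, 5 were lower when adjusted over the list alone against 0 over all genes. The class I gene H2-Q6 measured 7.89 ± 0.114 CPM in control and 2.61 ± 0.129 CPM in knockout islets (log2 fold change -1.59 ± 0.28, adjusted p = 0.684). H2-Q4 stood at -0.71 ± 0.19 (-0.45 without control replicate 2) and the class II gene H2-Aa at -0.70 ± 0.16. Reads of the H2-Q genes can be split among near-identical copies. The list's camera adjusted p was 9.15e-20, and 0.348 with an estimated correlation. That correlation was -0.0113, below the preset 0.01, so the higher value does not come from genes of the list varying together. The antigen presentation list shares 1 gene with the interferon list. Genes of different lists can still vary together, so the lower lists are not separate pieces of evidence.

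Inflammation genes and chemokines and the markers of macrophages were the other immune lists below the rest of the genes. Of 11 inflammation genes 9 had negative values (median -0.63), and 3 were lower when adjusted over the list alone against 0 over all genes. The interferon-induced chemokine gene Cxcl9 gave 11 and 25 counts in control and 1 and 1 in knockout libraries, a knockout level of 5.78% of control with a counting interval of 0.674% to 22.4%. The chemokine gene Ccl5 gave 20 and 15 against 4 and 0 counts, or 11.9% of control (3.07% to 33.2%). The cytokine gene Il6 had a log2 fold change of -1.92 ± 0.60 (-0.91 without control replicate 2) and the chemokine gene Cxcl16 of -0.63 ± 0.23. Camera's adjusted p was 7.14e-09, and 0.539 with an estimated correlation. The median was -1.28 without knockout replicate 2. All 15 tested macrophage markers had negative values (median -0.48), and 2 were lower when adjusted over the list alone against 0 over all genes. The pan-leukocyte gene Ptprc stood at -0.94 ± 0.24, the lysozyme gene Lyz2 at -0.93 ± 0.28, the lipopolysaccharide co-receptor gene Cd14 at -0.78 ± 0.27 and the cathepsin gene Ctss at -0.64 ± 0.18. The macrophage list had a camera adjusted p of 7.14e-09, and 0.734 with an estimated correlation. Its median was -0.28 without control replicate 1.

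**Figure D2:**
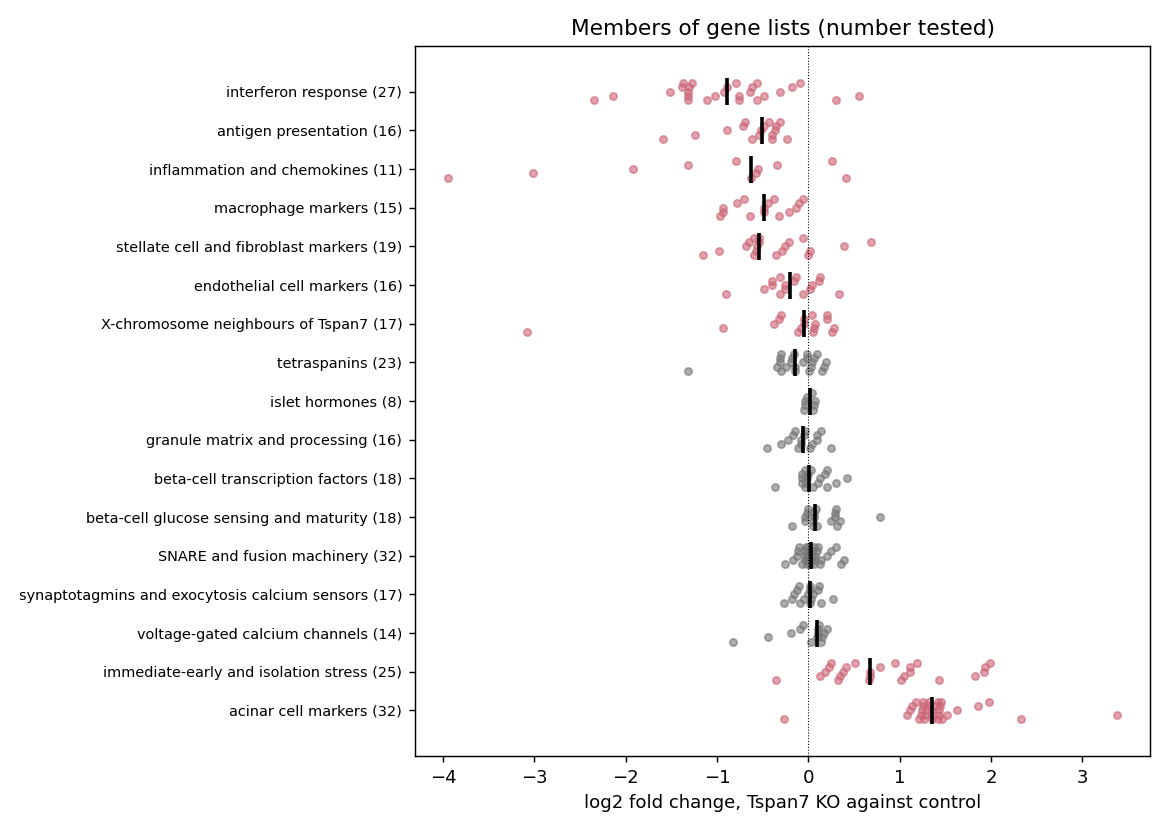
Log2 fold change of knockout against control for each tested member of 17 gene lists, with 1 point per gene, a black bar at the list's median, and in red the lists past camera at its preset correlation. Interferon genes centre on -0.89 and antigen presentation genes on -0.51, while the islet hormones centre on 0.02.

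The islet hormone genes showed no detectable difference. Their 8 log2 fold changes ran from -0.05 to 0.08, 4 of them positive and 4 negative, with a median of 0.02 and a camera adjusted p of 0.963. With 1 library left out the median ran from -0.07 without control replicate 2 and -0.08 without knockout replicate 2 to 0.10 without control replicate 1 and 0.14 without knockout replicate 1. Ins2 measured 6009 ± 453 CPM in control and 6197 ± 1262 CPM in knockout islets, with a 95% CI of the log2 fold change from -0.36 to 0.45. The interval was -0.46 to 0.39 for Ins1, -0.41 to 0.33 for the amyloid polypeptide gene Iapp, -0.40 to 0.37 for the glucagon gene Gcg, -0.35 to 0.47 for the somatostatin gene Sst and -0.33 to 0.48 for the pancreatic polypeptide gene Ppy. Hormone transcripts took between 2.11% and 2.34% of each library. Gcg measured 6700 ± 1216 CPM in control islets, above Ins2. How closely these counts follow the amount of insulin mRNA was not tested, so the result holds for the counts as deposited. Among 16 genes of the granule matrix and of prohormone processing the median was -0.06 (camera adjusted p = 0.416). The list passed as lower without control replicate 2 (median -0.18, adjusted p = 0.00986) and without knockout replicate 2 (-0.21, 0.00566), while its median was 0.09 without control replicate 1 and 0.07 without knockout replicate 1. Its smallest p was that of Vgf, a granule protein gene, at -0.45 ± 0.21 (-0.70 without control replicate 1, -0.15 without control replicate 2 and -0.30 without knockout replicate 1), followed by the granule membrane protein gene Ptprn at -0.23 ± 0.15 (-0.08 without knockout replicate 1 and -0.39 without knockout replicate 2). Slc30a8, the zinc transporter gene of insulin granules, stood at 0.25 ± 0.17 (0.48 without control replicate 1, 0.04 without control replicate 2 and 0.15 without knockout replicate 2).

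Genes of beta-cell identity and glucose sensing did not pass either in the comparison of all 4 libraries. The 18 transcription factors had a median of 0.01 (camera adjusted p = 0.494), -0.06 without control replicate 1, 0.15 without control replicate 2 and 0.03 without knockout replicate 1, with Myt1 at 0.42 ± 0.20 and Nkx2-2 at 0.20 ± 0.14. Myt1 stood at 0.76 without control replicate 1 and 0.15 without control replicate 2, and Nkx2-2 at 0.33 without knockout replicate 1 and 0.07 without knockout replicate 2. The 18 genes of glucose sensing and maturity had a median of 0.07, with 14 positive values (camera adjusted p = 0.0535). This list passed as higher in 5 alternatives, with upper-quartile scaling (0.0456), no low-count filter (0.0485) and the crossed pairing (0.0335), without control replicate 1 (median 0.15, adjusted p = 0.0150) and without knockout replicate 1 (0.23, 0.0213). Its median was 0.05 without control replicate 2 and -0.03 without knockout replicate 2. Npas4, which is in this list and in the immediate-early list, gave 43.7 ± 13.1 CPM in control and 75.5 ± 10.2 CPM in knockout islets. The phosphatase inhibitor gene Ppp1r1a stood at 0.35 ± 0.17 (0.57 without control replicate 1 and 0.15 without control replicate 2) and the incretin receptor gene Gipr at 0.31 ± 0.16 (0.18 without knockout replicate 1). Among 15 genes normally kept low in beta cells or raised on dedifferentiation the median was -0.06 (camera adjusted p = 0.375), with the lactate dehydrogenase gene Ldha at -0.74 ± 0.29 (-0.40 without control replicate 2). That list's median was -0.16 without control replicate 1, -0.17 without control replicate 2 and -0.34 without knockout replicate 1.

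Lists for the machinery of exocytosis, the process named in the title of the study, had medians close to 0, while single members ranged more widely. The 32 SNARE and fusion genes had a median of 0.02 and a range of -0.26 to 0.39 (camera adjusted p = 0.494), and their median was 0.04 without control replicate 1, -0.005 without control replicate 2 and 0.08 without knockout replicate 1. Rph3al, which encodes a Rab effector of granule release, stood at 0.39 ± 0.17, the SNARE gene Snap25 at 0.25 ± 0.14 (95% CI -0.07 to 0.56) and Rab3b at 0.35 ± 0.19. Rph3al stood at 0.61 without control replicate 1 and 0.19 without control replicate 2, Snap25 at 0.14 without knockout replicate 2, and Rab3b at 0.53 without control replicate 1, 0.19 without control replicate 2 and 0.15 without knockout replicate 1. Sytl5, a Rab27-effector gene that lies between Tspan7 and Lancl3, measured 76.6 ± 12.5 CPM in control and 88.1 ± 3.82 CPM in knockout islets (95% CI -0.16 to 0.56), with a log2 fold change of 0.38 without control replicate 1 and 0.04 without control replicate 2. The 17 synaptotagmins and other calcium sensors had a median of 0.01, while their mean was -0.01 and camera's direction was down (adjusted p = 0.738), and the median was 0.01, -0.05, -0.04 and -0.10 without control replicates 1 and 2 and knockout replicates 1 and 2 in turn. Syt7, the high-affinity calcium sensor gene, stood at 0.12 ± 0.13 (95% CI -0.18 to 0.42, and 0.07 without knockout replicate 2) and Syt4 at -0.27 ± 0.14 (-0.17 without knockout replicate 1). The 14 voltage-gated calcium channel genes had a median of 0.10, a mean of -0.03 and a range of -0.82 to 0.20 (camera direction up, adjusted p = 0.963). Their direction depended on the knockout library used, with a call as lower without knockout replicate 1 (median -0.17, adjusted p = 0.0497) and as higher without knockout replicate 2 (0.16, 0.0467), and a median of 0.04 without control replicate 2. The L-type channel gene Cacna1d stood at 0.20 ± 0.13 (95% CI -0.09 to 0.50) and the subunit gene Cacnb2 at 0.18 ± 0.13. The 21 potassium, sodium and other channel genes had a median of 0.04 and a mean of -0.08 (camera direction up, adjusted p = 0.963), and the median was 0.02 without control replicate 1 and without knockout replicate 1. The sodium channel gene Scn3a had the smallest p of these, at -0.43 ± 0.15.

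The remaining tetraspanins, related to Tspan7, did not pass as a list. Of 23 tested members 15 had negative values, with a median of -0.15 (camera adjusted p = 0.0756) that was -0.01 without control replicate 2. The leukocyte tetraspanin Cd53 had the smallest p, at 3.52 ± 0.129 CPM in control and 1.42 ± 0.243 CPM in knockout islets (log2 fold change -1.32 ± 0.37), beside the lower macrophage markers. Tspan8 stood at -0.35 ± 0.21 (-0.61 without control replicate 1 and -0.01 without control replicate 2) and Cd151 at -0.30 ± 0.17. The 22 integrins and tetraspanin partners ranked lower than other genes, with 16 negative values and a median of -0.16 (camera adjusted p = 0.0218, and an adjusted p of 0.734 with an estimated correlation). The protease gene Adam10 stood at -0.39 ± 0.15 (-0.21 without control replicate 2) and the integrin gene Itgav at -0.29 ± 0.12. The call was lost without control replicate 2 (adjusted p = 0.236, median -0.15) and without knockout replicate 2 (0.655, median -0.08), and the median was -0.26 without knockout replicate 1.

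Of the lists for the cytoskeleton, metabolism and growth, 4 ranked lower than other genes by small medians, and each has an adjusted p of 0.734 with an estimated correlation. These were the 24 actin and granule transport genes (median -0.08, camera adjusted p = 0.0178), 16 glycolysis genes (-0.12, 0.0241), 16 hypoxia genes (-0.18, 0.0315) and 21 cell cycle genes (-0.12, 0.0213). None of their members passed over all genes or when adjusted over the list alone. Examples were the membrane-actin linker gene Msn at -0.46 ± 0.14, the granule transport gene Mlph at -0.55 ± 0.21 (-0.35 without control replicate 2), the glycolytic gene Tpi1 at -0.37 ± 0.14, the glucose transporter gene Slc2a3 at -1.30 ± 0.53 (-0.38 without control replicate 2) and the topoisomerase gene Top2a at -0.61 ± 0.30 (-0.21 without knockout replicate 1 and -1.12 without knockout replicate 2). Each call depended on single libraries. The actin call was lost without control replicate 1 (median -0.05, adjusted p = 0.192) and knockout replicate 2 (-0.06, 0.126), and the median was -0.15 without control replicate 2 and also without knockout replicate 1. The glycolysis call was lost without control replicate 2 (median -0.07, adjusted p = 0.364) and knockout replicate 2 (-0.13, 0.0789), and the median was -0.20 without control replicate 1. The hypoxia call was lost without control replicate 2 (median -0.05, adjusted p = 0.323) and knockout replicate 1 (-0.26, 0.0816). The cell cycle call was lost without control replicate 1 (median -0.09, adjusted p = 0.353) and knockout replicate 1 (-0.06, 0.793), and the median was -0.25 without control replicate 2 and -0.22 without knockout replicate 2.

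With all 4 libraries no call was made for 31 nuclear genes of oxidative phosphorylation (median -0.04, camera adjusted p = 0.126), where Ndufa4 had the smallest p at -0.42 ± 0.16. The 26 genes of the unfolded protein response had a median of -0.08 (0.293), with Creld2 at -0.37 ± 0.14 and Sel1l at -0.27 ± 0.12. The 22 cholesterol synthesis genes had a median of 0.09 (0.416), with the sterol transporter gene Stard4 at 0.53 ± 0.19 (0.82 without control replicate 1 and 0.28 without control replicate 2), and the 35 cytosolic ribosomal protein genes one of -0.04 (0.375). The 13 mitochondrially encoded mRNAs had a median of 0.10 while their mean was -0.004 and camera's direction was down (0.963). Their levels were uneven, with mt-Nd5 at 9490 CPM and mt-Co2 at 5.14 CPM in control islets. Of these 5 lists, 3 passed as lower without control replicate 2 and also without knockout replicate 2. The 2 medians were -0.13 and -0.12 for oxidative phosphorylation (adjusted p = 0.0131 and 0.0119), -0.15 and -0.21 for the unfolded protein response (0.00665 and 0.00487) and -0.13 and -0.12 for ribosomal proteins (0.00260 and 0.0400). Without knockout replicate 1 the medians were 0.04, 0.03 and 0.03 for these 3 lists, and without control replicate 1 they were -0.02, -0.04 and 0.05. Cholesterol synthesis passed as higher without knockout replicate 2 (0.17, 0.0322), and its median was 0.06 without control replicate 1 and -0.07 without knockout replicate 1. The mitochondrial mRNAs passed as higher without knockout replicate 1 (median 0.33, adjusted p = 0.0259) and as lower without knockout replicate 2 (-0.23, 0.000970).

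Exocrine and stress transcripts were higher in knockout islets by camera, but the 2 control libraries differed more than the groups did. Acinar markers, the digestive enzyme genes of the exocrine pancreas, took 0.441% and 0.0185% of counts in control replicates 1 and 2, and 0.214% and 0.923% in knockout replicates 1 and 2. Of 32 tested markers 31 had positive values (median 1.35), none past the threshold over all genes or when adjusted over the list alone. The trypsin gene Prss3 had the smallest p, at 3.38 ± 1.17 (8.02 without control replicate 1 and 2.05 without knockout replicate 2). The list's mean log2 CPM differed by 2.36 between the groups and by 4.58 between the 2 control libraries and 2.20 between the 2 knockout libraries. Camera's adjusted p was 3.13e-07, and 0.734 with an estimated correlation. Without control replicate 2 the median was 0.38 (adjusted p = 0.424), and without knockout replicate 2 it was -0.18, while camera's direction was still up (adjusted p = 0.0400). It was 5.86 without control replicate 1 and 2.06 without knockout replicate 1. Of 25 immediate-early and isolation stress genes 24 had positive values (median 0.68), with Npas4, Egr2 at 1.05 ± 0.45 (0.62 without knockout replicate 2) and Klf4 at 0.68 ± 0.34 (1.20 without control replicate 1, 0.28 without control replicate 2 and 0.35 without knockout replicate 2) among them. Their mean differed by 0.86 between the groups, by 1.14 within control and by 1.10 within knockout. Camera's adjusted p was 1.09e-07, and 0.734 with an estimated correlation. The call was lost without control replicate 2 (median 0.32, adjusted p = 0.192) and without knockout replicate 2 (median 0.05, adjusted p = 0.664), and the median was 1.15 without control replicate 1 and 1.10 without knockout replicate 1. With the acinar mean as a covariate 5 calls besides the acinar one were lost. These were the immediate-early (median 0.08, adjusted p = 0.0954), stellate cell (-0.11, 0.149), glycolysis (-0.09, 0.331), hypoxia (-0.10, 0.253) and integrin (-0.08, 0.282) calls. The same covariate gave calls to 5 lists that had none. These were lower granule matrix genes (median -0.25, adjusted p = 1.64e-05), unfolded protein response (-0.19, 6.40e-06), ribosomal proteins (-0.15, 3.17e-05) and oxidative phosphorylation (-0.12, 0.00126), and higher lymph node and mesothelial markers (2.13, 0.00618).

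**Figure D3:**
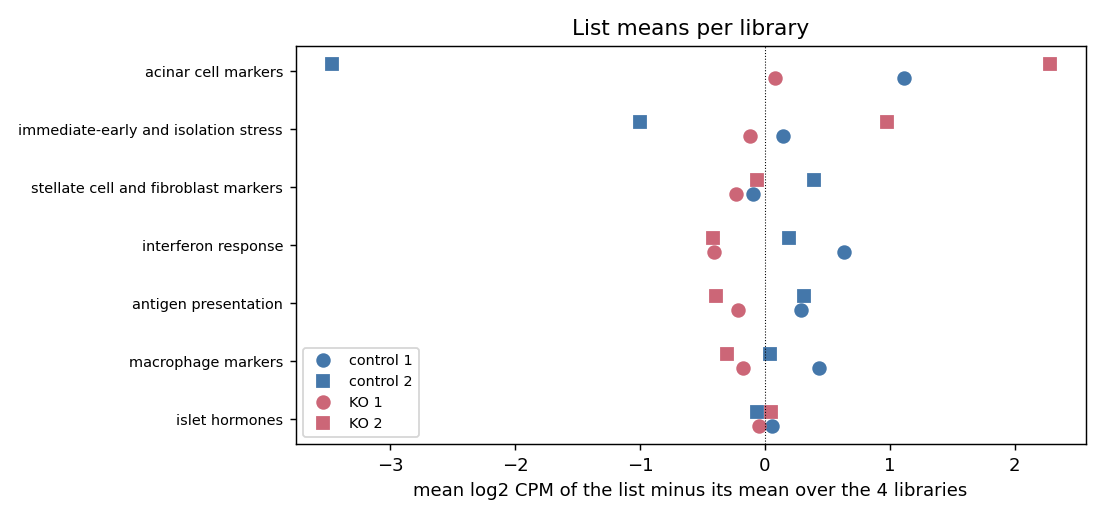
Mean log2 CPM of 7 gene lists in each library, minus the list's mean over the 4 libraries, with control in blue, knockout in red, circles for replicate 1 and squares for replicate 2. Acinar and immediate-early genes are lowest in control replicate 2 and highest in knockout replicate 2, while for interferon and antigen presentation genes both control libraries lie above both knockout libraries.

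Markers of vascular and connective tissue cells ranked lower. The 16 endothelial markers had a median of -0.21 (camera adjusted p = 0.00734, and an adjusted p of 0.734 with an estimated correlation), with Egfl7 at -0.91 ± 0.24 and the vascular cadherin gene Cdh5 at -0.48 ± 0.21 (-0.72 without control replicate 1, -0.19 without control replicate 2 and -0.30 without knockout replicate 2). The call was lost without knockout replicate 1 (median -0.13, adjusted p = 0.229), and the median was -0.31 without knockout replicate 2. The 19 stellate cell and fibroblast markers had a median of -0.54 (camera adjusted p = 8.78e-05, and an adjusted p of 0.734 with an estimated correlation), with the matrix genes Sparc at -0.65 ± 0.16 and Col3a1 at -0.68 ± 0.22. Their median was -0.03 without control replicate 2 (adjusted p = 0.424) and -0.81 without control replicate 1. No marker of either list passed over all genes or when adjusted over the list alone. With all 4 libraries the lists for other islet cells were not called, with medians of -0.05 for 12 alpha cell markers (camera adjusted p = 0.817), -0.01 for 10 delta cell markers (0.625) and -0.25 for 4 gamma cell markers (0.416). With 1 library left out these medians ran from -0.20 (without control replicate 1) to 0.07 (without knockout replicate 2) for alpha cells and from -0.15 (without knockout replicate 1) to 0.08 (without knockout replicate 2) for delta cells. For gamma cells they ran from -0.43 (without knockout replicate 1) to 0.01 (without control replicate 1). Nor were calls made for 13 ductal markers (median -0.12, adjusted p = 0.576, 0.02 without control replicate 1 and -0.02 without control replicate 2), 8 glial and neuronal markers (0.10, 0.416, -0.06 without control replicate 1, 0.23 without control replicate 2 and 0.01 without knockout replicate 1), 3 adipocyte markers (0.19, 0.817) or 3 lymph node and mesothelial markers (0.53, 0.416). The gamma cell list passed as lower with the replicate block (-0.23, 0.000420) but not with the crossed pairing (-0.21, 0.664). With all 4 libraries and no block, its genes Spp1 and Sertm1 stood at -1.70 and -0.56, while the hormone genes Ppy and Pyy stood at 0.08 and 0.06. Spp1 is also in the ductal list. The lymph node and mesothelial list, with 4 genes tested, passed as higher without control replicate 2 (1.73, 0.0368) and without knockout replicate 2 (1.10, 0.000107), and its median was 0.29 without control replicate 1 and -0.44 without knockout replicate 1.

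The fixed list of X-chromosome neighbours of Tspan7 had 17 tested genes and a median of -0.05, with 8 positive and 9 negative values. Only Lancl3 was lower when adjusted over the list alone. Camera's adjusted p was 0.0315, and 0.734 with an estimated correlation, and the call was lost without control replicate 1 (median -0.02, adjusted p = 0.605), knockout replicate 1 (-0.01, 0.158) or knockout replicate 2 (-0.13, 0.0504), with a median of -0.09 without control replicate 2. Xk, next to Lancl3 in gene order among the tested genes, stood at -0.32 ± 0.17 (-0.09 without control replicate 1 and -0.51 without control replicate 2). Gm14862, a gene that lies inside Lancl3 on the opposite strand, gave 19 and 11 counts in control and 3 and 3 in knockout libraries (log2 fold change -2.23 ± 0.63, adjusted p = 0.9997). Since the use of strand in counting is not given, its reads cannot be told apart from those of Lancl3.

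With 2 libraries per group the comparison had limited reach. In simulated data for these 16924 genes, 48% of genes changed by 2-fold and 4% of genes changed by 1.5-fold were called, so differences of those sizes in single genes could be missed here. The simulated changes were in genes with a mean log2 CPM of at least 1. The 134 calls made there also eased the adjusted threshold, against 1 call in the real comparison. The share found in the real comparison may therefore be lower.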

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

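Apart from the crossed pairing, which was chosen after the data were seen, every alternative here was fixed beforehand. Tspan7 stayed past the threshold in all 15 alternatives (log2 fold change from -9.54 to -9.23, adjusted p from 1.41e-229 to 0.00578). The counts of other genes moved most. With no low-count filter edgeR called 15 genes higher and 47 lower, with the likelihood ratio test 2 and 14, and with the acinar covariate 0 and 2. DESeq2 called 0 and 4, and an adjusted p under 0.10 gave 0 and 2. With 1 library left out, where the lone library is assumed to vary like the others, there were 0 to 33 genes higher and 1 to 15 lower, the highest of both without control replicate 1. The cause of these changes was not tested. Limma-voom and the other scalings, filters and thresholds gave 0 and 1.

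Same-numbered libraries deviated in opposite directions from their group means (correlation across genes -0.300), and no label ties a number to an animal or day. The replicate block gave 1 gene higher and 5 lower, and the crossed pairing of replicate numbers 1 and 1.

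Lancl3 kept its direction in all 15 alternatives (-3.41 to -2.68). It passed in 7 of them, DESeq2 among these, with adjusted p over all alternatives from 8.57e-23 to 0.9998, the latter with limma-voom. Of 1109 values of 74 named genes besides Tspan7, 1057 kept their direction and their side of the threshold, 38 passed it (18 genes) and 14 turned in sign. With 1 library left out, 38 of the 74 genes turned or moved by over 1.5 times. Those that turned were genes near 0 and never past the threshold. With 1 library left out the log2 fold change ran from -0.27 to 0.17 for Ins1, from -0.18 to 0.24 for Ins2, from -0.22 to 0.12 for Iapp, from -0.19 to 0.19 for Gcg, from -0.18 to 0.33 for Sst, from -0.12 to 0.25 for Ppy and from -0.14 to 0.34 for mt-Nd5. With the acinar covariate it was -0.11 for Ins2 and -0.11 for Sst.

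Of the 14 lists past camera, 0 were called with an estimated correlation (smallest adjusted p 0.348) and 0 with fry (0.273). The estimated correlation also called 0 lists in the simulated data, where the interferon list was lowered by construction, so its loss of every call decides nothing by itself. The interferon, antigen presentation, inflammation and macrophage lists, 4 in all, were called in every one of 11 alternatives at the preset correlation, and the other 10 lost the call or turned in at least 1. The acinar median was -0.0661 with the acinar covariate, which removes that signal by construction, and ran from -0.18 to 5.86 with 1 library left out. The median of the X-chromosome neighbours was 0.0463 with no low-count filter, which added genes of low count to the list, while camera's direction stayed down. Of the 22 lists not called with all 4 libraries, 10 gained a call in at least 1 alternative at the preset correlation and 12 gained none.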

Other observations

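The tests of macrophage markers, of a shared animal state and of a deletion spanning Lancl3 were chosen only after the results they measure had been seen, and the clock genes were picked out after Hlf was seen among the top genes.

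Clock-controlled transcription factors shared the direction of Hlf. Tef and Per3, which belong to the circadian output and feedback loops, had log2 fold changes of 0.46 ± 0.14 and 0.58 ± 0.17 (SE, adjusted p = 0.9997 each in edgeR), and both knockout libraries lay above both control libraries for each. Nr1d1, a repressor of the clock, measured 118 and 25.8 CPM in the control libraries against 136 and 181 CPM in the knockout libraries. Npas2, the only 1 of 7 opposite-phase genes with a negative log2 fold change, measured 10.1 and 28.3 CPM against 11.9 and 9.41 CPM. Control replicate 2 thus stood apart in both Nr1d1 and Npas2. Arntl, also of the opposite phase, was higher in knockout, at 29.5 and 15.9 CPM against 35.9 and 37.2 CPM (log2 fold change 0.69 ± 0.27).

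A candidate explanation is a difference in the time of day at collection, which the labels do not give and which requires genes that peak with Hlf to be higher and those of the opposite phase to be lower. The 7 genes that peak with Hlf had a median log2 fold change of 0.82, all positive, and the 7 of the opposite phase a median of 0.13, with 1 negative. The difference of 0.695 exceeded what permuting the genes gives (exact one-sided permutation p = 0.00583 over 3432 assignments, with genes taken as independent), but the opposite arm was not lower. Because the clock genes were chosen after values were seen, this p is descriptive only. Timing therefore cannot be told apart from other sources of the difference, an untested effect of the Tspan7 genotype among them. The difference was 0.389 without control replicate 2, 0.477 without knockout replicate 2 and 1.63 without control replicate 1.

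For the lower interferon genes, loss of macrophages from the knockout isolates and exocrine content were weighed. Macrophage markers had a smaller shift than interferon genes (difference of medians 0.407, bootstrap 95% interval 0.00065 to 0.867, permutation p = 0.0271). The margin is narrow, and both the interval and the permutation take genes as independent. The estimated correlations were 0.545 for the macrophage list and 0.314 for the interferon list. This comparison therefore cannot decide whether a loss of macrophages is the whole cause. With the acinar mean as a covariate the interferon median was -1.13. That fit left fewer residual degrees of freedom than the 2 of the main fit and also called lists that had no call without it. It therefore cannot decide whether exocrine content plays a part. Within control, the library with more acinar transcripts had the higher interferon mean. Within knockout, the acinar means differed by 2.20 and the interferon list's means by 0.00913. The list's mean log2 CPM differed by -0.83 between knockout and control, 1.88 times the widest gap within a group (0.44, between the control libraries), a ratio that was 3.44 for antigen presentation, 1.96 for inflammation and 1.21 for macrophage markers. The adjusted p with an estimated correlation was 0.539, in a test that also missed a list lowered by construction, so that an interferon state that differs between single animals, through infection or housing for instance, stays open and cannot be told apart from an effect of the Tspan7 genotype, which is an untested hypothesis.

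For the lower Lancl3, one deletion spanning both genes and a change across the neighbourhood were weighed. The 5 tested genes between Tspan7 and Lancl3 (Xk, Cybb, Dynlt3, Sytl5 and Rpgr) had a median log2 fold change of -0.0499 and a range of -0.32 to 0.28, against -9.42 for Tspan7, which argues against a single deletion. Among 49 tested neighbours, 25 on each side of Tspan7 with Lancl3 left out, 1 had an unadjusted p under 0.05 (1.71 expected by chance, exact hypergeometric p = 0.826). That gene, Gm14862, lies inside Lancl3, and 0 of the other 48 had a p that small. These counts argue against changes as large as that of Lancl3 across the region. A small shift of the region could pass unseen, since 2 libraries per group seldom give a small p for one. A separate sequence difference at Lancl3 carried along with the Tspan7 allele, and an effect of Tspan7 loss on Lancl3, may both account for the lower counts and were not tested.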
